A study of Mus musculus with 7 samples.

How the data were processed

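Total RNA of treated and non-treated fibroblasts was purified on silica columns, reverse transcribed and labelled indirectly with Cy3 or Cy5, and both cDNAs were hybridised to the same array, per the labels' protocols. The protocols also speak of organs and of a pool made from control animals, which differs from the source names, where both channels are fibroblasts; the source names were followed. The scanner software, background correction and normalization are not given in the sources used here.

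The deposited values form 1 table of log2 ratios for 20355 probes on 7 arrays. Neither the log base nor the direction is stated in the labels. The base was read from the values, and the direction was assumed. After a constant of each array was taken off, the deposited values clustered at the log2 of ratios of small whole numbers (for example 1:1, 1:2 and 1:3), which fits base 2, a single scaling constant per array without an intensity-dependent correction, and whole-number intensities after background subtraction. The constants ran from -0.632 to 0.45. Each array also held 1 repeated extreme value, on 163 to 1614 spots. It was 16.054 to 17.06 where the treated sample was in Cy5 and -16.713 to -15.978 where it was in Cy3, and in size it differed from 16.61, the log2 of 100000, by the constant of the array. It was taken as a stand-in for a spot with no signal in 1 channel and treated as not measured, a choice made after the values were seen. The deposited ratios were read as treated over non-treated by a rule fixed in advance, which kept this reading unless arrays of opposite dye correlated below -0.3. The lowest such value was -0.119 (-0.148 with the repeated values kept), but arrays of the same dye within a time reached only 0.086 to 0.232, so the rule could hardly have given the other reading. The sign of the repeated value does not settle the direction either. It fits turned ratios if the missing channel was always Cy3, and Cy5 over Cy3 if it was always the non-treated sample. The direction of the ratios is thus an assumption of every result. The other reading is given beside the main list calls and the probe calls in values filtered by their ratio. It was not run for lists in those filtered values. The medians of the 4 arrays at 3 h were -0.014, 0.049, -0.103 and -0.065, and those of the 3 arrays at 10 h were -0.04, -0.006 and 0.005. Between 13262 and 15157 spots were measured at 3 h, and between 16395 and 17766 at 10 h. No centring was added.

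Probes were named through the platform annotation. Of 20355 probes, 14030 had 1 symbol, 5 had several and 6320 had none, and no gene was named from a probe with several. Gene identifiers of 13994 probes were found in the gene table of the RefSeq reference, and 0 symbols changed. Together the probes with 1 symbol covered 9930 genes.

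Each probe was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with a mean for each time point and a term for the dye of the treated sample, over all 7 arrays. Probes needed values on at least 3 arrays at 3 h and 2 at 10 h, which left 11559. The 3 h mean, the 10 h mean and their difference were each tested two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The arrays within a time point were compared, and 0 pairs held mostly identical values.

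A family of 25 gene lists was fixed before the data were examined. It covered the immediate early and serum response, p53 targets, apoptosis, G1/S and DNA replication, G2/M and mitosis, histones, the unfolded protein response and ATF4 targets, heat shock proteins, the interferon response, NF-kB and inflammatory genes, cholesterol and fatty acid synthesis, glycolysis and hypoxia, oxidative stress and metallothioneins, cytosolic ribosomal proteins, oxidative phosphorylation, the proteasome, extracellular matrix and fibroblast markers, actin and SRF targets and the lysosome. It also held markers of adipocytes, skeletal muscle, macrophages and lymphocytes, epithelium, neurons and glia, and erythroid and liver transcripts. Lists were tested on gene means over probes, with the pre-ranked form of camera applied to the moderated statistics (preset correlation 0.01), because camera itself takes no missing values. Camera with an estimated correlation and fry were run on the 4272 genes with values on all arrays, where 20 lists had at least 5 genes. With the estimated correlation no list passed in any comparison. Fry asks whether the genes of a list move on balance one way and does not compare them with other genes. A median given relative to all genes is the list's median less that of the 6573 genes in the fit.

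Named genes followed a rule fixed in advance. Up to 12 probes in each direction were to be named among those that passed with the same sign on every array. Where fewer than 5 passed, the 10 probes with 1 symbol and the smallest p were named as not passing. The rule also allowed up to 4 members of each list with the smallest p. The numbers used, 4 for a list that passed and 1 otherwise, were not part of the rule. Values are given as the mean ± SD over arrays, and the adjusted p is that of the fit. The fit includes the dye term, so its log2 ratio can differ from that mean.

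The fit was tested on simulated data made from the spread and missing values of the real arrays. Over 5 runs on 11559 probes at 3 h, 4% of changes of 1 log2 unit, 60.8% of changes of 2 units, 91.2% of changes of 3 units and 97.6% of changes of 4 units were found, and 5.06% of unchanged probes had an unadjusted p under 0.05. A ribosomal shift of 0.35 at 10 h was called in 5 of 5 runs, with 0 calls among 120 tests of other lists. The simulated noise was independent between probes, while the correlation estimated within the ribosomal list on the real arrays was 0.385. These runs thus do not test false list calls where the genes of a list vary together.

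Alternatives fixed in advance were the other reading of the direction, no dye term, arrays with the treated sample in Cy5 only, centring, quantile normalization, scaling to 1 spread, other filters on missing values, a robust variance model, each time fitted alone, array weights, the replicate number as a block, gene means, a floor of 0.5 on the log2 ratio, and each array left out in turn. Keeping the repeated extreme values was added after the data were examined. Treating values at ratios of whole numbers up to 8, 12 or 20 as not measured was added then too. With ratios up to 8 left out, the probe fit was also run with the other direction. Figures were drawn with matplotlib 3.10.9.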

Results

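Expression was profiled in NIH3T3 cells, an immortalised mouse embryonic fibroblast line, that overexpressed Acid1, at 3 h and at 10 h after treatment. Each of 7 arrays carried treated fibroblasts in 1 dye and non-treated fibroblasts in the other. There were 4 arrays at 3 h, 2 of them with the treated sample in Cy5 and 2 in Cy3, and 3 arrays at 10 h, 2 with the treated sample in Cy5 and 1 in Cy3. The labels give neither the nature of the treatment nor what Acid1 stands for, and no probe was annotated with Acid1 as a symbol or synonym, so its own level is not analysed here. Every value was read as a log2 ratio of treated over non-treated cells, a direction that the labels do not state, for 20355 probes, of which 14030 had 1 gene symbol. Because the non-treated RNA was the second channel of each array, each time point was tested as a ratio against 0, which leaves out the spread of the control itself. Nothing in the labels says that the arrays came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

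Far more values lay at ratios of small whole numbers on the 3 h arrays than on the 10 h arrays. Between 56.05% and 63.44% of the measured values on the 3 h arrays lay at the log2 of a ratio of whole numbers no larger than 8, such as 1:1 or 1:2, after the constant of that array was taken off (tolerance 0.0016). At 10 h the share was 11.98% to 13.07%. Grids shifted by small fixed amounts gave on average 1.64% to 3.2%. Such a ratio can arise where a spot rests on a few intensity units above background in each channel, which would limit the precision at 3 h. Intensities are not among the values, so low signal at 3 h was not measured. The 6 pairs of 3 h arrays correlated at a Pearson r of 0.076 to 0.232 across probes, which are not independent replicates. At 10 h the pair with the same dyes correlated at 0.086, and the dye-swapped array at -0.076 and -0.119 with the others.

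**Figure D1:**
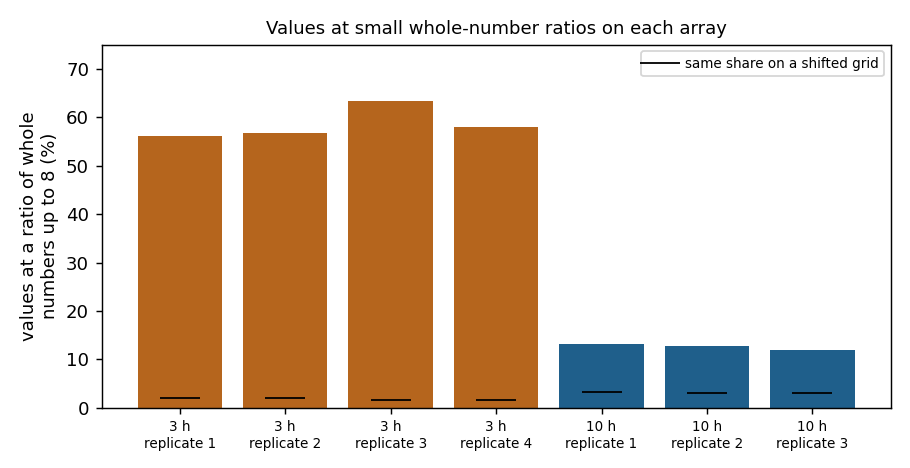
Share of measured values (%) on each array that lay at the ratio of 2 whole numbers up to 8, with 3 h arrays in brown, 10 h arrays in blue, and black dashes for the mean share found on grids shifted by fixed amounts. The 4 arrays at 3 h lie between 56.05% and 63.44%, and the 3 arrays at 10 h between 11.98% and 13.07%.

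The first comparison asks which transcripts differed between treated and non-treated fibroblasts at 3 h. Genes of the extracellular matrix and fibroblast list and of the unfolded protein response and ATF4 target list were higher than the rest of the measured genes. Over the 35 measured matrix genes the median log2 ratio was 0.184, which is 0.315 above the median of all 6573 genes, and 22 of the 35 were above 0. Over the 23 measured genes of the unfolded protein response and ATF4 targets it was 0.167, or 0.298 above all genes, and 15 of the 23 were above 0. Both lists passed limma's camera test with a preset correlation, each with an adjusted p = 0.0133, and neither passed with an estimated correlation (adjusted p = 0.744 for both). With the ratios read in the other direction, as Cy5 over Cy3, 0 lists passed at 3 h, the stress list turned to -0.117 and the matrix list was 0.109. No single probe passed.

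Among the matrix genes, Sparc, a secreted glycoprotein that binds collagen, had a log2 ratio of 0.72 ± 0.29 (SD, n = 4), above 0 on 4 of 4 arrays, and Pcolce, which enhances procollagen processing, had 0.68 ± 0.59 (n = 4). Mmp14, a membrane-anchored matrix metalloproteinase, had 0.89 ± 1.09 (n = 4), and Col1a1, a chain of type I collagen, had 1.11 ± 0.47 (n = 3). Their adjusted p-values in limma were between 0.301 and 0.409. Among the stress genes, the transcription factor Atf4 had 0.52 ± 0.27, the endoplasmic reticulum chaperone Calr 0.52 ± 0.25, the chaperone Hspa5 0.44 ± 0.34 and asparagine synthetase, Asns, 0.56 ± 0.47 (SD, n = 4 each). All 4 genes were above 0 on all 4 arrays, with adjusted p-values of 0.38 to 0.458. No member of either list passed over all genes, and 0 passed when adjusted over the list alone. On single arrays the median of the stress list lay 0.169 to 0.62 above the array's median, so it was higher on 4 of 4 arrays. The matrix list lay above it on 3 of 4 arrays, at 0.335 to 0.473, and below it on replicate 3, at -0.169.

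Neither list passed in fry (adjusted p = 0.858 for the matrix list and 0.496 for the stress list). The call of the matrix list also ended without 3 h replicate 1, 2 or 4 or 10 h replicate 2 (adjusted p = 0.231, 0.167, 0.908 and 0.064, with a median of 0.134 without replicate 4), and that of the stress list without the same arrays (0.231, 0.167, 0.135 and 0.0734).

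Of 11559 probes tested with limma at 3 h, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.201. An unadjusted p under 0.05 was reached by 1577 probes, or 13.6%, against 578 expected by chance. The fit shared 1 spread per probe over both times, but the 3 h arrays varied more. Their scaled median absolute deviation was 0.8184 to 1.1535, against 0.5323 to 0.5841 at 10 h. The median over all probes at 3 h was -0.149 and was not centred. Both can raise the count, so the excess does not show changed probes. In simulated data with the same spread at both times, the same fit found at 3 h 4% of changes of 1 log2 unit, 60.8% of changes of 2 units and 91.2% of changes of 3 units. The real 3 h arrays varied more, so these shares may be too high for them. Smaller changes of single genes were thus mostly not detectable here. The 10 named probes with the smallest p are given as values that did not pass, all with an adjusted p of 0.201. Gpc4, a cell-surface heparan sulfate proteoglycan, had a log2 ratio of -1.89 ± 0.18 (SD, n = 4). Sparcl1, a secreted relative of Sparc, had -1.73 ± 0.33, C2cd3 -1.87 ± 0.55, the ion channel subunit Asic2 -1.68 ± 0.47, the ubiquitin ligase Herc2 -2.03 ± 0.55 and the GTPase Gimap3 -2.06 ± 0.66 (n = 4 each), and Iqsec3 had -2.31 ± 0.30 (n = 3). Higher values were found for Hspa14, a member of the Hsp70 family (2.75 ± 0.75, n = 3), the calcium channel subunit Cacna1f (2.37 ± 0.94, n = 3) and the SUMO protease Senp2 (1.86 ± 0.64, n = 4). A second probe of Hspa14 had a fitted log2 ratio of -1.03, so the probes of that gene disagreed in sign.

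The second comparison asks the same at 10 h. At the preset correlation, ribosomal protein genes were higher as a group than the rest of the measured genes. So were genes of cholesterol and fatty acid synthesis and, to a smaller extent, of oxidative phosphorylation. Of 49 measured ribosomal protein genes, 45 were above 0, with a median log2 ratio of 0.324, which is 0.349 above the median of all genes (adjusted p = 1.75e-10 in camera with a preset correlation, but adjusted p = 0.546 with an estimated correlation). Of 17 measured genes of cholesterol and fatty acid synthesis, 15 were above 0, with a median of 0.36, or 0.385 above all genes (adjusted p = 0.000197, and 0.546 with an estimated correlation). Of 47 genes of oxidative phosphorylation, 31 were above 0, with a median of 0.155, or 0.18 above all genes (adjusted p = 0.00432, and 0.793 with an estimated correlation). With the ratios read in the other direction 0 lists passed at 10 h, with the ribosomal list at 0.13, the sterol list at 0.013 and oxidative phosphorylation at 0.069 (adjusted p = 0.85, 0.952 and 0.911).

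The shifts were small and much alike on the arrays of both dye orientations. Relative to the median of the array, the ribosomal list lay at 0.389 ± 0.059 (mean ± SD, n = 3 arrays), the sterol list at 0.359 ± 0.094 and the oxidative phosphorylation list at 0.217 ± 0.055, each above 0 on 3 of 3 arrays. Rps15a had a log2 ratio of 0.63 ± 0.11, Rps27 0.60 ± 0.25 and Rps29 0.55 ± 0.17 (SD, n = 3 each), while Rpl13 went the other way at -1.055 ± 1.07 (n = 3). In the sterol pathway, HMG-CoA synthase, Hmgcs1, had 0.66 ± 0.15, the methylsterol oxidase Msmo1 0.82 ± 0.12, squalene synthase, Fdft1, 0.71 ± 0.15 and squalene epoxidase, Sqle, 0.66 ± 0.18 (n = 3 each), all above 0 on 3 of 3 arrays. Of the respiratory chain genes, Ndufa13 had 0.56 ± 0.12, Cox6c 0.54 ± 0.13 and Ndufa2 0.52 ± 0.08 (n = 3 each), and Cox8a 1.51 ± 2.38 (n = 2). The adjusted p of each of these genes was 1, and 0 members of the 3 lists passed when adjusted over the list alone.

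**Figure D2:**
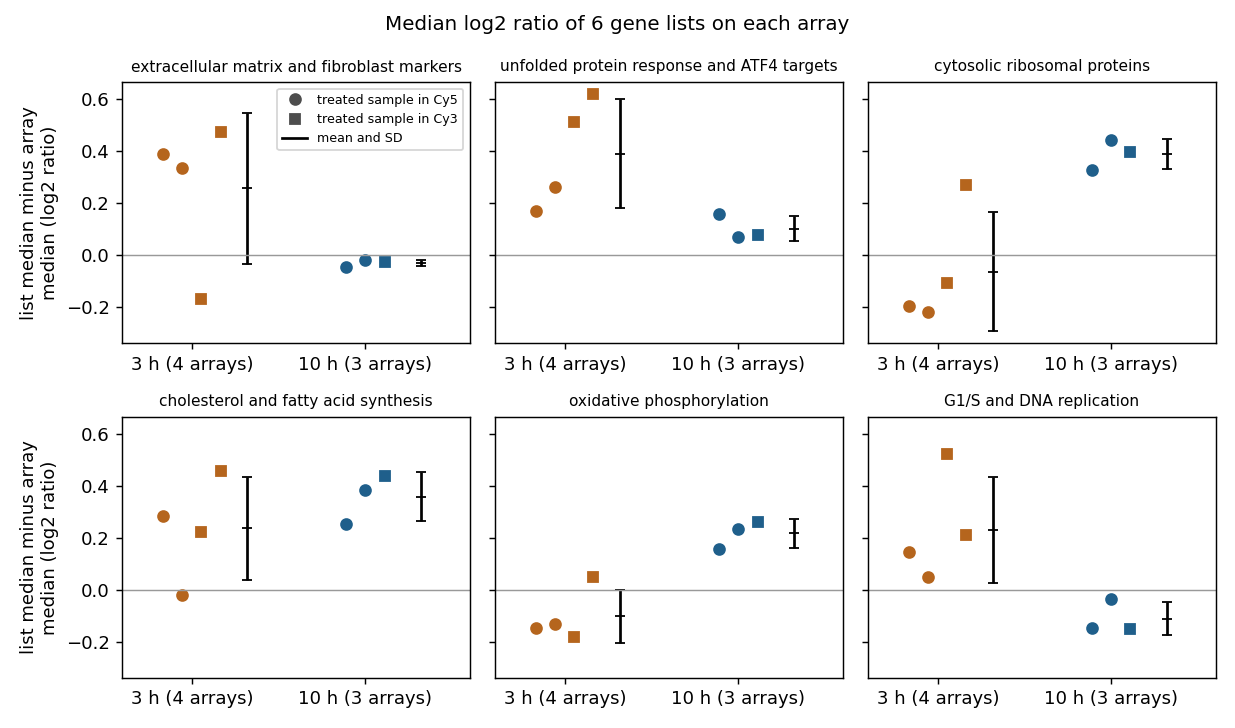
Median log2 ratio of 6 gene lists on each array, minus the median of all genes on that array, with 3 h arrays in brown, 10 h arrays in blue, circles for the treated sample in Cy5, squares for Cy3, and bars for the mean ± SD. The ribosomal list lies between 0.327 and 0.444 on the 3 arrays at 10 h, and between -0.22 and 0.272 on the 4 arrays at 3 h.

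No list passed in fry at 10 h (adjusted p = 0.662 for the ribosomal and the sterol list and 0.927 for oxidative phosphorylation). The sterol call ended without 10 h replicate 2 (adjusted p = 0.0503) and the oxidative phosphorylation call without 10 h replicate 1, 2 or 3 (0.137, 0.0669 and 0.563), while the ribosomal call passed without each array in turn, at a median of 0.335 to 0.55, the highest without 10 h replicate 3.

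Of the 11559 probes, 0 passed at 10 h in limma. The smallest adjusted p was 0.988, and 448 probes, or 3.9%, had an unadjusted p under 0.05, which is below the 578 expected by chance. The spread shared with the more variable 3 h arrays can lower this count. The 10 named probes with the smallest p did not pass, with adjusted p-values of 0.988 to 0.994. They included Celsr3, an adhesion receptor of the cadherin family (2.85 ± 0.12, n = 2), Zfpm1, a cofactor of GATA factors (3.07 ± 0.06, n = 2), Slain2, a microtubule-binding protein (-1.79 ± 0.29, n = 3), Snx29 (-2.65 ± 0.73, n = 3) and the chromatin remodelling protein Ep400 (-2.78 ± 0.50, n = 2). The others were Ltbr, the lymphotoxin beta receptor (2.22 ± 0.64, n = 2), Srgap3 (-1.95 ± 0.80, n = 2), Atmin (1.77 ± 2.11, n = 3), Grtp1 (1.72 ± 1.29, n = 3) and Fign (-1.52 ± 1.29, n = 3). The ranking came from the fit with its dye term, whose values can differ from these means. With each array left out in turn, the fitted log2 ratio ran from 2.196 to 2.57 for Atmin and from -1.927 to -1.779 for Fign. Another probe of Ep400 had a fitted log2 ratio of 2.42, and another probe of Atmin had -0.52, so the probes of Ep400 and Atmin disagreed in sign.

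**Figure D3:**
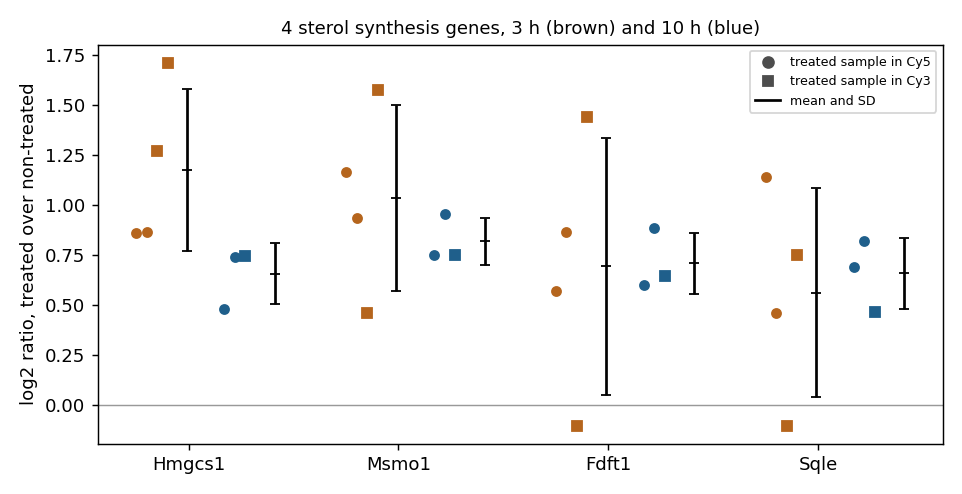
Log2 ratio of treated over non-treated fibroblasts for 4 sterol synthesis genes on each array, with 3 h arrays in brown (n = 4), 10 h arrays in blue (n = 3), circles for the treated sample in Cy5, squares for Cy3, and bars for the mean ± SD. Hmgcs1 and Msmo1 are above 0 on every array drawn, and Fdft1 and Sqle are below 0 on 1 array at 3 h each.

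The sterol genes were also measured at 3 h, where the list did not pass (adjusted p = 0.119, median 0.16 above all genes, 10 of 17 above 0). Hmgcs1 had the smallest p of that list at 3 h, with a log2 ratio of 1.18 ± 0.41 (n = 4, adjusted p = 0.251 in limma over all genes). On probes with values on all 7 arrays the list passed at 3 h (0.199 above all genes, adjusted p = 0.0108), as it did in camera on genes with all values (adjusted p = 0.0259), but not with an estimated correlation on those genes (adjusted p = 0.744) or in fry (0.725). At 3 h, 2 members of the list were higher when adjusted over the list alone. The difference between the times was not significant for this list (adjusted p = 0.946).

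The third comparison asks whether the response differed between 10 h and 3 h. The ribosomal and oxidative phosphorylation lists were higher at 10 h than at 3 h, and the matrix list and the list for G1/S and DNA replication were lower. The ribosomal list differed by 0.525 relative to all genes, with 41 of 49 genes higher at 10 h (adjusted p = 0.000125 in camera with a preset correlation, but 0.937 with an estimated correlation). The oxidative phosphorylation list differed by 0.281, with 35 of 47 genes higher (adjusted p = 0.0287, and 0.937 with an estimated correlation). The matrix list differed by -0.303, with 24 of 35 genes lower (adjusted p = 0.0287, and 0.937), and the replication list by -0.306, with 19 of 24 lower (adjusted p = 0.0364, and 0.937). With the ratios read in the other direction 0 lists passed, with differences of 0.322, 0.11, -0.141 and -0.056 in the same order.

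Rps29 went from -0.57 ± 0.17 at 3 h (n = 4) to 0.55 ± 0.17 at 10 h (n = 3), Rpl27 from -0.71 ± 0.50 to 0.46 ± 0.09 and Rpl34 from -0.58 ± 0.47 to 0.49 ± 0.01. Rps27 went from -0.53 ± 0.60 to 0.60 ± 0.25. Of the oxidative phosphorylation genes, Ndufs6 went from -0.81 ± 0.31 to 0.40 ± 0.34, Ndufa2 from -0.57 ± 0.57 to 0.52 ± 0.08, Ndufa13 from -0.40 ± 0.40 to 0.56 ± 0.12, and Sdhd, a subunit of succinate dehydrogenase, from -0.92 ± 0.77 to 0.04 ± 0.64. Sparc went from 0.72 ± 0.29 to -0.22 ± 0.22, Col1a1 from 1.11 ± 0.47 to -1.12 ± 1.13 and Mmp14 from 0.89 ± 1.09 to -0.31 ± 1.12, while Col4a1, a basement membrane collagen, went the other way, from -0.45 ± 0.45 to 0.71 ± 1.21. In the replication list, the DNA polymerase subunits Pole and Pold1 went from 1.10 ± 0.53 to -0.52 ± 0.36 and from 0.26 ± 0.29 to -0.36 ± 0.29, thymidine kinase, Tk1, from 0.51 ± 1.28 to -0.20 ± 0.25, and Rfc5, a subunit of the clamp loader, from -1.24 ± 1.62 to -2.75 ± 2.86 (SD, 2 to 4 arrays each). None of these genes passed, with adjusted p-values of 0.608 to 0.773 in limma, and 0 members of the 4 lists passed when adjusted over the list alone.

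In fry the 4 lists had adjusted p-values of 0.473, 0.799, 0.998 and 0.998. The ribosomal call passed without each array in turn. The oxidative phosphorylation call ended without 3 h replicate 1 or 3 (adjusted p = 0.166 and 0.11) or 10 h replicate 1, 2 or 3 (0.102, 0.0679 and 0.271), and the replication call without 3 h replicate 1 or 3 (0.166 and 0.229) or 10 h replicate 2 or 3 (0.395 and 0.518). The matrix call ended without 3 h replicate 1, 2 or 4 (0.216, 0.37 and 0.785) or 10 h replicate 1, 2 or 3 (0.102, 0.244 and 0.0611). The matrix difference was -0.164 without 3 h replicate 4 and -0.484 without 10 h replicate 3, and the replication difference was -0.468 without 3 h replicate 2.

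Of the 11559 probes, 0 passed in the comparison of the times (smallest adjusted p 0.566), and 932, or 8.1%, had an unadjusted p under 0.05, against 578 expected by chance. The median difference over all probes was 0.143 and was not centred, which can raise this count. The 10 named probes with the smallest p all had an adjusted p of 0.566. Hspa14 went from 2.75 ± 0.75 to -0.98 ± 0.41, and its second probe had a fitted difference of 1.1. Gpc4 went from -1.89 ± 0.18 to 0.10 ± 0.29, Slain2 from 0.90 ± 0.37 to -1.79 ± 0.29, Pik3ip1, an inhibitor of PI3 kinase, from 2.22 ± 1.96 to -0.81 ± 0.13, and the chromatin remodelling subunit Arid1b from -2.24 ± 0.49 to 0.64 ± 1.15. The lipid transporter Abca6 went from -1.38 ± 1.07 to 1.39 ± 1.21, Cacna1f from 2.37 ± 0.94 to -0.38 ± 1.31, Atmin from -0.56 ± 2.43 to 1.77 ± 2.11, Snx29 from 1.02 ± 0.57 to -2.65 ± 0.73 and Fign from 1.24 ± 1.24 to -1.52 ± 1.29. Other probes disagreed in sign for Arid1b (fitted differences of -1.21 and -1.54), Abca6 (-0.19), Atmin (-0.72) and Snx29 (0.77).

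The other 19 lists passed in no comparison. Across the comparisons, the adjusted p-values of lists that did not pass ran from 0.119 to 0.925 at 3 h, from 0.371 to 0.978 at 10 h and from 0.18 to 0.997 for the difference. Median values relative to all genes were as follows at 3 h and 10 h. For growth and division, the immediate early and serum response list was at -0.125 and -0.208, the G2/M and mitosis list at 0.19 and -0.119 and the histone list at 0.171 and -0.039. For stress and death, the p53 target list was at 0.187 and -0.053, the apoptosis list at 0.144 and -0.015, the heat shock list at 0.1 and -0.067 and the list of oxidative stress genes and metallothioneins at 0.064 and 0.033. The interferon list was at -0.018 and -0.085 and the NF-kB and inflammatory list at 0.061 and -0.12. The glycolysis and hypoxia list was at 0.131 and -0.067, the proteasome list at 0.022 and 0.06, the lysosome list at 0.194 and -0.026 and the actin and SRF target list at 0.145 and -0.014. Markers of other cell types did not pass either. The adipocyte list was at 0.014 and 0.121, the muscle list at 0.003 and -0.256, the macrophage and lymphocyte list at 0.18 and 0.018, the epithelial list at 0.144 and -0.211, the neuronal and glial list at -0.331 and 0.206 and the erythroid and liver list at -0.449 and -0.014, with 5 to 10 measured genes each. The median and the camera direction differed in sign for some of these lists, for example the p53 targets at 10 h, whose mean log2 ratio was 0.31. Adjusted over the list alone, 1 gene of the erythroid and liver list was lower at 10 h and 1 heat shock gene was lower in the difference, and 0 members of the others passed.

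The single genes with the smallest p in 4 of these lists illustrate the spread at 3 h. Apaf1, which activates caspase 9, had -1.16 ± 0.50, Btg2, an antiproliferative gene induced by p53, had -0.84 ± 0.26, profilin, Pfn1, had 0.62 ± 0.26 and aldolase A, Aldoa, had 0.73 ± 0.46 (SD, n = 4 each), with adjusted p-values of 0.273, 0.287, 0.325 and 0.32 in limma.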

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

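The tests of dye bias, of dim 3 h arrays and of spots near background reported here were chosen after the results they bear on had been seen; those of bright spots, apart from the count of list genes and the spread given with them, and of other splits of the arrays were not.

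The response of 4 lists differed between the times at the preset correlation, but of 0 with an estimated correlation (adjusted p = 0.937 for each) or with the ratios read in the other direction. Relative to all genes, the ribosomal list was 0.525 higher at 10 h than at 3 h and the oxidative phosphorylation list 0.281 higher, while the matrix list differed by -0.303 and the list for G1/S and DNA replication by -0.306 on the log2 scale. Of the 35 splits of the 7 arrays into 4 and 3, only the real one called 4 lists, and the highest of the others called 3. So few splits, with so close a second, cannot exclude chance. The real split also separates the arrays by their share of small whole-number ratios, so the count does not single out the time. The number of lists called by the real split fell to 1 to 3 without any 1 array and to 2 with array weights. The split that separates the dyes was fitted without the dye term and called 0 lists. For probes the real split called 0, as did the highest of the others, so that 35 of 35 splits called as many was fixed from the start and decides nothing.

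The first pattern is that ribosomal protein genes lay higher than other genes at 10 h, at the preset correlation only. If the ratios are treated over non-treated, a dye bias would lie in the dye term, where the list's median relative to all genes was -0.06, against a 10 h median of 0.349. If they are Cy5 over Cy3, the 10 h median falls to 0.13 (adjusted p = 0.85) and the shift is what a dye bias would give, so a dye bias stays open. A bias shared by all spots that never sat at a small whole-number ratio, as 29 of the 49 ribosomal genes never did, is argued against by 1242 such genes outside the called lists, whose median at 10 h relative to all genes was -0.007 (SD 0.246 over genes), but intensities are not among the values, so a bias that grows with intensity stays open. Dim 3 h arrays stay open for the lower value at 3 h, because the list's 3 h median of -0.059 with small whole-number ratios left out comes from a filter on the ratio and not on the intensity. A response to Acid1 or to the treatment was not tested apart from these.

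The second pattern is that sterol and fatty acid genes lay higher than other genes at 10 h, at the preset correlation only. The list's median dye coefficient was 0.014 relative to all genes, against a 10 h median of 0.385, but with the ratios read as Cy5 over Cy3 the 10 h median was 0.013 (adjusted p = 0.952), so a dye bias stays open. The same 1242 genes lay at -0.007, but only 4 of the 17 sterol genes met their criterion, so a bias of bright spots stays open as well. A response of the sterol pathway to the treatment, and a difference in medium, serum or cell density between the 2 channels, were not tested apart from these and stay open.

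The third pattern is the low agreement between 3 h arrays. Among replicates 1, 2 and 4, the Pearson r rose in 3 of 3 pairs when small whole-number ratios were left out, for replicates 1 and 2 from 0.232 to 0.37, but the filter acts on the ratio and not on the intensity, so this does not tie the disagreement to dim spots. For replicate 3 it rose in 0 of 3 pairs. It went from 0.078 to -0.06 with replicate 1, from 0.076 to 0.066 with replicate 2 and from 0.089 to 0.051 with replicate 4. With ratios up to 20 left out, the Pearson r was -0.072, -0.116 and 0.113 in the same order. With replicate 4 the Spearman value rose from 0.108 to 0.191 with ratios up to 8 left out. Spots near background stay open for all 4 arrays. On replicate 3 those 1242 genes had a median of -0.245 relative to the array, against 0.042 to 0.131 on the other 3 h arrays. No biological explanation was tested.

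In 6 of 88 groups of 4 values at 3 h, 1 array lay far from the other 3, and chance flags about 1 in 20 groups. Replicate 4 had the highest value of Sparc (1.158, the others 0.545 to 0.595) and of Rpl27 (0.024, the others -1.048 to -0.912). The median of the immediate early list relative to the array was 0.361 on replicate 4, with the others at -0.362 to -0.244, and that of the adipocyte list was -0.53, with the others at 0.225 to 0.302. Replicate 3 had the highest value of H4c1 (1.355, the others -0.065 to 0.128) and of Slc7a5 (0.705, the others 0.163 to 0.202).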

How the results depend on the processing

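The settings with the repeated extreme values kept, with ratios of small whole numbers left out, and with camera on complete genes were chosen after the data were examined. Values are list medians relative to all genes on the log2 scale unless a p is named; the difference is 10 h less 3 h, and the cause of each change was not tested.

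With the other reading of the ratio direction, 0 lists were called at 3 h, 0 at 10 h and 0 for the difference. The stress list at 3 h turned to -0.117 and the matrix list was 0.109. At 10 h the sterol list was 0.013, with the test turned to the other direction, the ribosomal list 0.13 and oxidative phosphorylation 0.069. For the difference the replication list was -0.056, with the test turned, the ribosomal list 0.322, oxidative phosphorylation 0.11 and the matrix list -0.141. With the treated sample in Cy5 only, 1 list was called at 3 h and 2 for the difference; no longer called were the stress list (0.275), the replication difference (-0.323) and the oxidative phosphorylation difference (0.256). With values on all 7 arrays the replication difference lost its call (-0.302, adjusted p = 0.0503) and the sterol list at 3 h gained one (0.199). With a looser filter on missing values, which still needed at least 1 value at each time, 0 lists were called at 3 h and 1 for the difference. Calls ended there for the stress list (0.287), the matrix list (0.261), and the differences of replication (-0.248), oxidative phosphorylation (0.324) and the matrix list (-0.245). With array weights 2 lists were called for the difference, while replication (-0.285) and oxidative phosphorylation (0.18) lost their calls. With the replicate number as a fixed block the matrix difference was -0.276 and not called (adjusted p = 0.6), though replicate numbers showed no sign of pairing the times.

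With the repeated extreme values kept, 6 probes were called at 3 h, 2 higher and 4 lower, and 2 lists for the difference, while replication (-0.311) and oxidative phosphorylation (0.114) lost their calls. Without ratios of whole numbers up to 8, 35 probes and 4 lists were called at 3 h, and the replication difference lost its call (-0.322). Up to 12, 56 probes and 5 lists were called at 3 h, 5 lists at 10 h and 4 probes for the difference; the p53 list at 10 h was lower at -0.219, and the replication difference lost its call (-0.265). Up to 20, 39 probes were called at 3 h, 1 at 10 h and 13 for the difference, while the stress list (0.334) and the replication difference (-0.227) lost their calls. Up to 8 without 3 h replicate 3, 0 probes and 4 lists were called at 3 h, among them the stress (0.444) and matrix (0.459) lists. Still called were oxidative phosphorylation at 10 h (0.241) and the matrix difference (-0.553), while the differences of replication (-0.269) and oxidative phosphorylation (0.231) lost their calls.

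With an estimated correlation 0 lists were called at 3 h, 0 at 10 h and 0 for the difference. The adjusted p was 0.744 for the matrix and 0.744 for the stress list, 0.546 for the ribosomal, 0.546 for the sterol and 0.793 for the oxidative phosphorylation list at 10 h, and 0.937 for the ribosomal, 0.937 for the oxidative phosphorylation, 0.937 for the matrix and 0.937 for the replication difference. In fry 0, 0 and 0 lists were called, with an adjusted p of 0.858 and 0.496 at 3 h, 0.662, 0.662 and 0.927 at 10 h, and 0.473, 0.799, 0.998 and 0.998 for the difference, in the same order. Camera on genes with all values called 5 lists at 3 h, and the replication difference lost its call (adjusted p = 0.0805).

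With each array left out in turn, 0 to 2 lists were called at 3 h, 1 to 3 at 10 h and 1 to 3 for the difference. The stress list ran from 0.286 to 0.385 and the matrix list from 0.134 to 0.428 at 3 h, and at 10 h the ribosomal list from 0.335 to 0.55, the sterol list from 0.347 to 0.568 and oxidative phosphorylation from 0.189 to 0.233. Among the differences, replication ran from -0.468 to -0.242, oxidative phosphorylation from 0.251 to 0.415 and the matrix list from -0.484 to -0.164.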

Other observations

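Everything in this part was chosen after the data were examined. With values at ratios of whole numbers up to 8 treated as not measured, 4071 probes remained and limma called 35 at 3 h, 33 lower and 2 higher, 15 of them with 1 gene symbol. With the ratios read in the other direction, as Cy5 over Cy3, 0 of the 4071 were called (smallest adjusted p 0.385), so these calls hold only for the assumed direction. The filter acts on the ratio itself, so it takes out many values at exactly 1:1 and is not neutral. As in the unfiltered fit, 1 spread per probe was shared by both times and the values were not centred. Both can raise the count of calls at 3 h. The SE values below thus do not measure the spread at 3 h alone. For Dbp, the SD over arrays was 0.723 at 3 h and 0.193 at 10 h. Lower were Sparcl1 (log2 ratio -1.73, SE 0.19, adjusted p = 0.0224), Dbp, a transcription factor under circadian control (-1.79, SE 0.26, adjusted p = 0.0384), the ubiquitin ligases Znrf1 (-1.56, SE 0.21, adjusted p = 0.0297) and Herc2 (-2.03, SE 0.27, adjusted p = 0.0281), Snx18 (-1.18, SE 0.16, adjusted p = 0.033), the antiproliferative gene Btg2 (-1.05, SE 0.17, adjusted p = 0.0439) and glutamine synthetase, Glul (-1.06, SE 0.17, adjusted p = 0.0439). The other lower probes with 1 symbol were those of Rbms2 (log2 ratio -2.35), Cdk12 (-2.00), Txndc16 (-1.78), Btbd9 (-1.69), Asic2 (-1.68), Snx29 (-1.55) and Ccdc88c (-1.27). This probe of Snx29 is not the one named in the comparisons above, whose mean at 3 h was positive. Pik3ip1, an inhibitor of PI3 kinase, was called higher (adjusted p = 0.0384), but its mean was 1.89 ± 2.26 (SD, n = 3) and the fitted value of 2.53 rests largely on 3 h replicate 1, at 4.45. At 10 h the same values gave 0 calls. Of the 35 probes, 27 were also called with ratios up to 12 left out and 19 with ratios up to 20 left out. Without 3 h replicate 3 as well, 0 probes were called among 5642 (smallest adjusted p 0.0698). No other array was left out of these values, and fewer arrays and more probes alone could end the calls.

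Lists were tested in the same filtered values with camera at the preset correlation only. An estimated correlation and the other ratio direction were not run there, and on the unfiltered values 0 lists passed with either. At 3 h the lists that passed were the unfolded protein response and ATF4 targets (0.443 relative to all genes, adjusted p = 0.000117) and the extracellular matrix list (0.332, adjusted p = 0.000232). Sterol and fatty acid synthesis (0.201, adjusted p = 0.00366) and actin and SRF targets (0.255, adjusted p = 0.0107) passed as well. At 10 h the immediate early and serum response list was lower (-0.202, adjusted p = 0.0326), beside the ribosomal, sterol and oxidative phosphorylation lists, which were again higher. For the difference, the unfolded protein response and ATF4 target list was lower (-0.376, adjusted p = 0.00665), as it was with ratios up to 12 left out (-0.485) and without 3 h replicate 3 (-0.424). These p-values use the preset correlation. On the unfiltered values, camera with an estimated correlation gave an adjusted p of 0.937 for the stress difference. It gave 0.793 for the immediate early list at 10 h.

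The 33 probes that were lower at 3 h in these values, none of which was called with the other direction, were unevenly spread over the probe numbers of the array. With the numbers divided into 10 equal blocks, the last, from 18320 to 20355, held 14 of the 33, but 467 of the 4071 probes tested. The median log2 ratio at 3 h of all probes fitted in that block was -0.144, and it ran from -0.26 to -0.036 over the 10 blocks.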
